A study of Mus musculus with 4 samples.

How the data were processed

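Poly(A) RNA from gonadotropes, the pituitary cells that make luteinizing hormone (LH) and follicle-stimulating hormone (FSH), was sequenced from male mice of 10 to 12 weeks and mixed strain. The cells had been sorted by flow cytometry, per the labels' protocols, whereas the series' design text speaks of bulk profiling of pituitaries. The sample labels were followed. The 4 libraries comprised 2 from controls and 2 from mice with a conditional knockout of Gata2 (cKO), grouped by the genotype in the labels. Libraries were made with the Universal plus mRNA-seq kit and sequenced to a stated depth of about 30000000 paired-end reads per sample, per the labels' protocols. The labels do not say whether the libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical.

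Reads were processed with STAR 2.5.1b and featureCounts 1.5.0-p1 on the mm10 build, per the submitters' processing notes. The annotation release, the strand setting and the treatment of reads with several matches are not given in the sources used here. The deposited table holds estimated counts for 54532 genes, with no scaling between libraries. Of the deposited values 4.5% were not whole numbers, and 13.4% of those above 0, so some reads had been divided between genes. Each row of the table has a gene identifier. Names and positions were taken from GENCODE M21, which uses the same build, and 54495 of the identifiers matched once their version was left off (53315 with it).

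Counts were rounded to whole numbers. Genes were filtered with filterByExpr (a minimum count of 10 and a minimum total of 15, by group), which left 17349 genes, and scaled with TMM factors. The main test was the two-sided quasi-likelihood F-test of edgeR 4.0.16 with package defaults, under R 4.3.3, with group as the only term and Benjamini-Hochberg adjusted p under 0.05 as the threshold. The standard error (SE) of a log2 fold change was its size divided by the square root of F. All log2 fold changes are cKO minus control. Levels are CPM (counts of a gene in each 1000000 of the library) scaled by TMM, and log2 CPM values for comparing libraries used a prior of 0.5 CPM. Where a group had no count, a fold is a lower bound against a floor of 3 counts per library. Such bounds cover counting error only, since reads without molecular identifiers are not independent molecules.

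Before the data were examined, 27 gene lists were fixed from general knowledge, along with the rule for named genes, the tests and most alternatives. The 26 lists with at least 3 tested members were tested with camera in limma 3.58.1, two-sided, at a preset inter-gene correlation of 0.01, with adjustment over the lists. The list of posterior lobe pituicyte markers had too few tested members. An estimated correlation and fry were alternatives. Named genes were Gata2, Fshb, Lhb, Cga, Gnrhr and Grem1, then up to 12 genes per direction with the largest log2 fold changes. The latter needed an adjusted p under 0.05, an average log2 CPM of at least 2 and both cKO libraries on the same side of both control libraries. Symbols made of Gm and a number, those ending in Rik, identifiers without a symbol and pseudogenes marked -ps were passed over. Up to 4 members with the smallest p were named from each list of gonadotrope, signalling, stress and other pathways, and up to 2 with the highest level from each list of other cell types or RNA quality. Genes outside this rule are said to have been chosen after their values were seen. A gene that the rule names is not reported here.

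Alternatives were DESeq2 size factors, upper-quartile factors and library size only, no filter, a filter of 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, the legacy and robust forms of edgeR's test, the replicate number as a block, other thresholds, and each library left out in turn. Added after seeing the data were edgeR's newer quasi-likelihood method, counts without rounding, libraries thinned to the smallest total and mitochondrial genes left out. Lists without Fshb, Grem1 and Lhb, and lists without called genes, were added then too. The default in this edgeR version proved to be the legacy form, so that alternative is identical to the main test.

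The tests were tried on simulated counts for this comparison, with 200 of 15472 genes changed. The changed genes were drawn from those with an average log2 CPM of at least 2, so recovery at lower levels was not tried. The main test recovered 20.9% of genes changed by a factor of 2, 58.2% at a factor of 4 and 72.7% at a factor of 8, and 6.48% of its calls were false. In the same simulation the false share of calls was 52.7% for DESeq2, 7.14% for limma-voom and 1.96% for edgeR's newer quasi-likelihood method. The simulated counts used dispersions that edgeR had estimated from these libraries, so these shares depend on that setting. With 15535 simulated genes, camera called 10 of 10 shifted lists of 20 genes at the preset correlation and 0 of 10 with an estimated correlation. Simulated genes varied independently of each other, so this trial does not bear on lists whose genes vary together.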

Results

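Gene expression was measured in sorted gonadotropes of control and Gata2 cKO male mice, with 2 libraries per group. The sample labels give sorted cells and the series' design text whole pituitaries, so how pure the cells were is open for every level given here. Gata2 codes for a zinc-finger transcription factor, and the comparison asks which transcripts differ when it is deleted in gonadotropes. Total estimated counts were 10646909 and 21135301 in control replicates 1 and 2, and 15541553 and 18362182 in cKO replicates 1 and 2. At least 1 count was found for 15220, 21628, 17383 and 18293 genes in the same order. Genes with 1 to 9 counts made up 4.95% to 10.2% of those detected, so a count of 0 does not show that a transcript was absent. Pearson's r of log2 CPM across genes was 0.889 between the controls and 0.902 between the cKO libraries. Control replicate 2 correlated more closely with the cKO libraries (0.917 and 0.928) than with control replicate 1, which stood apart. The Y-linked gene Ddx3y had 143 ± 5.32 CPM in controls and 142 ± 9.22 in cKO (SD, n = 2 each), and Xist had 57, 38, 0 and 0 counts, in libraries labelled male.

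Gata2 transcripts fell in cKO gonadotropes. Gata2 (ENSMUSG00000015053.14, mm10 chromosome 6, 88193891 to 88207032) had 537 and 526 CPM in the controls and 221 and 214 in the cKO libraries. Its log2 fold change was -1.29 (SE 0.14, edgeR adjusted p = 0.0473), which left 41.0% of the control level. The count covers the whole gene and includes exons that may lie outside the deleted part. The adjusted p is close to the threshold and was 0.0620 with a filter of 1 CPM in 2 libraries.

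The transcript of the FSH beta subunit and that of the BMP antagonist gremlin 1 fell as well. Fshb (ENSMUSG00000027120.6, chromosome 2, 107056140 to 107059656) went from 2880 ± 542 to 715 ± 137 CPM (SD, n = 2), a log2 fold change of -2.01 (SE 0.18, adjusted p = 0.0381 by edgeR). Grem1 (ENSMUSG00000074934.3, chromosome 2, 113746164 to 113758646) went from 157 ± 59.7 to 6.98 ± 1.68 CPM, a log2 fold change of -4.49 (SE 0.37, adjusted p = 0.0263). The study's title names FSH deficiency and loss of gremlin expression, and what it was based on is not given in the sources used here. It may rest on these libraries, so the direction of Fshb and Grem1 is not independent evidence. Fshb had an adjusted p of 0.0531 with a filter of 1 CPM in 2 libraries.

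**Figure D1:**
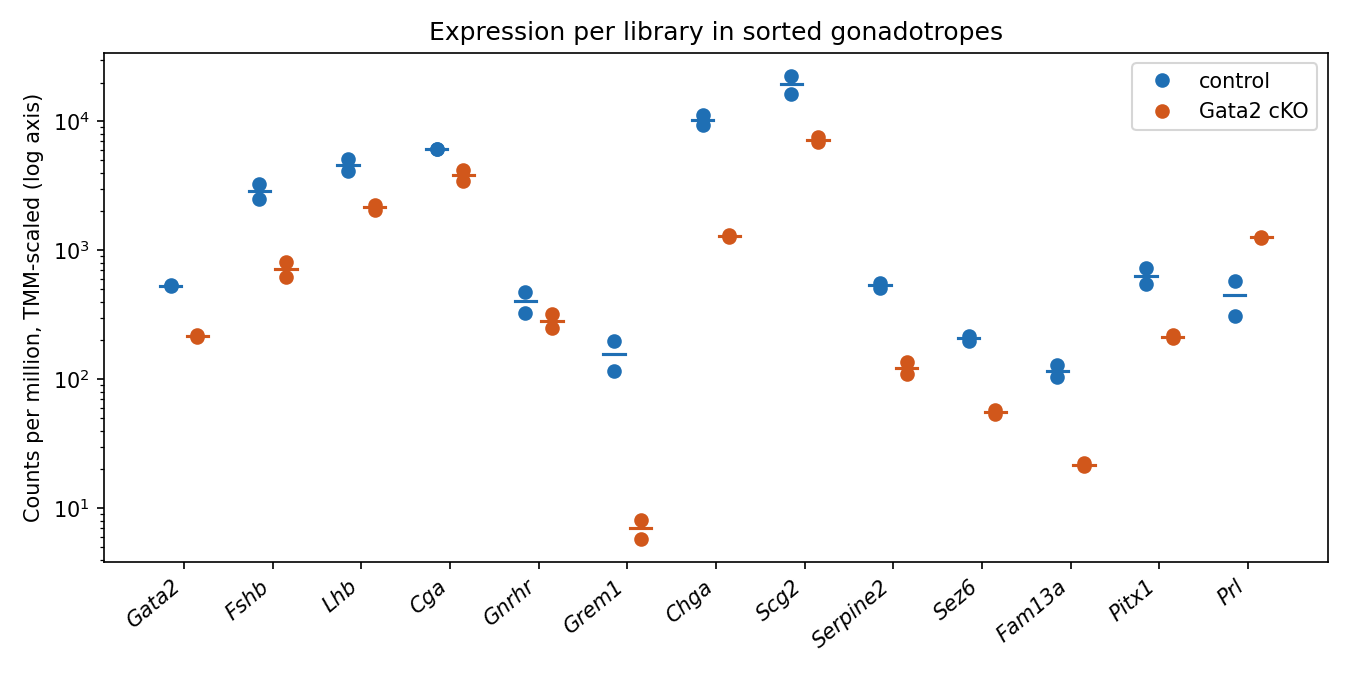
Expression of 13 genes in each of the 4 libraries, in TMM-scaled CPM on a log axis, with points for libraries and bars for group means. Grem1 lies at 199 and 115 CPM in the controls and at 8.17 and 5.79 in the cKO libraries, and Prl is the gene drawn that is higher in both cKO libraries.

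Across the 17349 genes tested, 8 fell and 2 rose. Besides Gata2, Fshb and Grem1, the genes that fell were Chga, Scg2, Serpine2, Sez6 and Fam13a. Chga codes for chromogranin A, a protein of secretory granules, and went from 10320 ± 1280 to 1296 ± 29.7 CPM (log2 fold change -2.99, SE 0.12, edgeR adjusted p = 0.000404). Scg2, which codes for the granule protein secretogranin II, went from 19410 ± 4240 to 7189 ± 434 CPM (log2 fold change -1.43, SE 0.14). Serpine2, a serine protease inhibitor, changed by -2.12 (SE 0.17), Sez6 by -1.90 (SE 0.18) and Fam13a by -2.42 (SE 0.24). The genes that rose were Gm21887 on the X chromosome (log2 fold change 3.05, SE 0.28) and Gm47283 on the Y chromosome (2.96, SE 0.31), named after their values were seen. Their counts were not whole numbers in any library, so some of their reads had been divided between features and the level of each is uncertain. The 2 calls may be 1 signal. At an unadjusted p under 0.05 there were 1221 genes, and DESeq2 called 943, of which 422 were higher, and limma-voom 256, of which 136 were higher. With a filter of 1 CPM in 2 libraries the 3 calls were Chga, Grem1 and Serpine2, and glmTreat against a factor of 1.5 called 2 genes, both lower. The count was 66 without control replicate 1 (26 higher), 681 without control replicate 2 (537 higher), 73 without cKO replicate 1 (22 higher) and 100 without cKO replicate 2 (23 higher). Higher genes outnumbered lower ones without control replicate 2, with limma-voom and without a filter (128 of 253 calls higher).

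**Figure D2:**
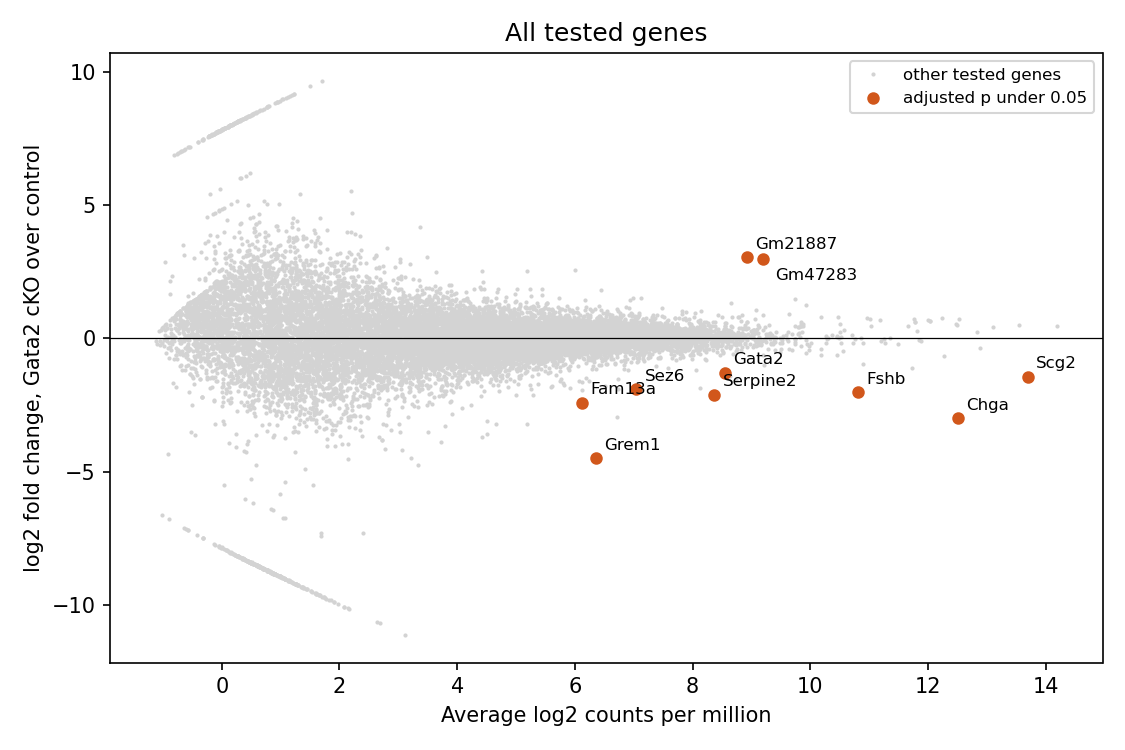
Log2 fold change of cKO over control against average log2 CPM for the 17349 tested genes, with the 10 genes at an adjusted p under 0.05 named. The diagonal bands at the edges are genes with no count in 1 group, whose fitted values are not measurements of a fold.

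Genes of gonadotrope identity were lower as a group. Of 19 tested members 15 were lower in cKO, and the median log2 fold change was -0.31 (camera adjusted p = 7.45e-10, but adjusted p = 0.370 with an estimated correlation). Over all genes tested 1 member fell, Fshb, and adjusted over the list alone 5 fell: Fshb, Pitx1, Lhb, Cga and Isl1. The pituitary transcription factor gene Pitx1 had a log2 fold change of -1.57 (SE 0.17, edgeR adjusted p = 0.0575 over all genes). Lhb, for the LH beta subunit (ENSMUSG00000100916.3, chromosome 7, 45420820 to 45421897), had -1.10 (SE 0.13, adjusted p = 0.0777). Cga, for the common alpha subunit (ENSMUSG00000028298.10, chromosome 4, 34893779 to 34907370), had -0.68 (SE 0.11, adjusted p = 0.212). Gnrhr, for the receptor of gonadotropin-releasing hormone (ENSMUSG00000029255.8, chromosome 5, 86180754 to 86197901), had -0.50 (SE 0.22, adjusted p = 0.706). Lhb overlaps Ruvbl2 and Cga overlaps Platr9 on the opposite strand, and the strand setting of the counts is not known. Ruvbl2 had 2259 counts and Platr9 662 over all libraries. Both are far below Lhb (32177 to 85778 counts per library) and Cga (53624.5 to 128418). Without control replicate 2 the median was -0.14. In the same cKO libraries lactotrope markers and mitochondrially encoded transcripts were higher, with medians of 0.72 and 0.65.

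Genes of secretory granules and prohormone processing were also lower as a group. Of 22 tested members 18 were lower, with a median of -0.18 (camera adjusted p = 5.49e-11, but adjusted p = 0.370 with an estimated correlation). Chga and Scg2 fell over all genes tested, and adjusted over the list alone Chgb, Pcsk1 and Rab27b fell too. The other 17 members did not pass. Of these Cpe (0.01, SE 0.12), Scg3 (0.02, SE 0.14) and Pam (-0.09, SE 0.18), chosen after their values were seen, changed little, as did Pcsk2 (-0.02, SE 0.20). Without called genes the camera adjusted p at the preset was 0.00108 and the median -0.17. Chgb, for chromogranin B, had a log2 fold change of -0.97 (SE 0.12) and Pcsk1, for a prohormone convertase, stood at 50.0% of its control level. Without control replicate 1 the median was -0.11. The lactotrope and mitochondrial lists moved the other way in the same libraries.

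BMP antagonists and activin-binding proteins gave a call that rested on Grem1. Of 11 tested members Grem1 was the 1 that fell, over all genes and adjusted over the list alone. The camera direction was down (adjusted p = 0.0398, but adjusted p = 0.527 with an estimated correlation), while the median log2 fold change was 0.16 and the mean -0.32. The median was -0.72 without control replicate 1, 0.27 without control replicate 2, -0.45 without cKO replicate 1 and -1.04 without cKO replicate 2. Bmper had -1.05 (SE 0.37), Bambi -1.31 (SE 1.09) and Fstl1 1.81 (SE 2.33). Without Grem1 the adjusted p was 0.964, and it was above the threshold without any 1 of the 4 libraries (0.0919 to 0.717). It was also above the threshold with no filter (0.159), upper-quartile factors (0.0560) and library size only (0.0558).

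BMP target genes were not called (camera adjusted p = 0.576, 4 of 11 members higher). Id2, a BMP-responsive inhibitor of DNA binding, rose adjusted over the list alone, with a log2 fold change of 1.10 (SE 0.23), but not over all genes (adjusted p = 0.360). Id3 had 2.66 (SE 1.75) and Smad6 -0.71 (SE 0.61). The camera direction was up and the mean 0.11, while the median was -0.25. BMP ligands, receptors and SMADs had an adjusted p of 0.887 and 0 of 18 members past the threshold, with Smad4 at 0.58 (SE 0.25), Smad1 at 0.52 (SE 0.28), Bmp8a at -3.25 (SE 2.16) and Bmp6 at -0.76 (SE 0.51). In the activin and inhibin pathway (adjusted p = 0.964) Inhbb, for the inhibin beta B subunit, fell adjusted over the list alone (-1.90, SE 0.26) and not over all genes (adjusted p = 0.108). Tgfbr3, for the inhibin co-receptor betaglycan, had -0.55 (SE 0.19) and Skil 0.54 (SE 0.25).

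Other signalling lists were not called by camera. In GnRH receptor signalling (24 members, adjusted p = 0.238), Prkcb (-1.03, SE 0.17) and Plcb3 (-1.77, SE 0.36) fell and Gnas (0.48, SE 0.11) rose adjusted over the list alone, and 0 passed over all genes. Prkcd had 1.18 (SE 0.34). The fry test of change in either direction gave this list an adjusted p of 0.00707. GATA and FOG factors had 5 tested members and an adjusted p of 0.391. Gata3 had 38, 19, 0 and 0 counts, Zfpm1 a log2 fold change of -0.83 (SE 0.43), Lmo2 2.31 (SE 1.81) and Ldb1 -0.11 (SE 0.22).

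**Figure D3:**
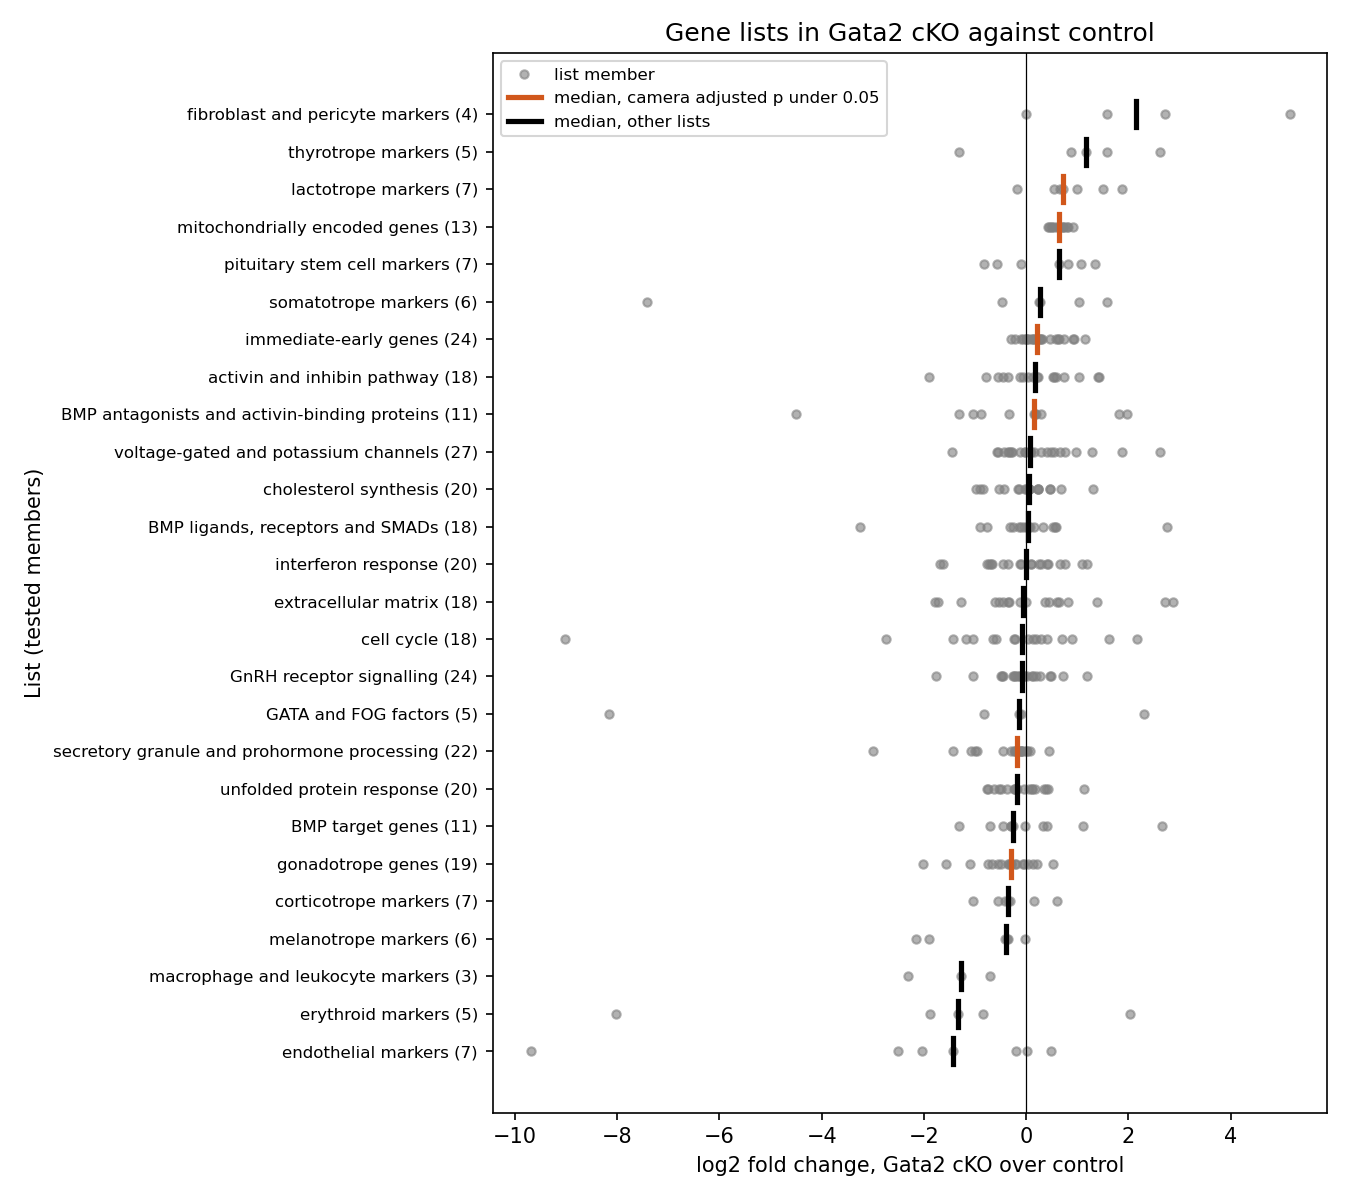
Log2 fold change of cKO over control for the tested members of 26 gene lists (grey points) with the list medians (bars), coloured where the camera adjusted p was under 0.05 at the preset correlation. The 6 coloured medians lie between -0.31 and 0.72, and members near -8 or below have no or nearly no counts in the cKO libraries.

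Immediate-early genes were higher as a group. Of 24 members 18 were higher, with a median of 0.22 (camera adjusted p = 0.000348, but adjusted p = 0.370 with an estimated correlation). Klf6 rose adjusted over the list alone (0.91, SE 0.19), and 0 members passed over all genes. Zfp36 had 0.46 (SE 0.12), Ier3 0.93 (SE 0.31) and Socs3 0.59 (SE 0.20). Other well-expressed members, chosen after their values were seen, changed little. Fos had -0.006 (SE 0.12), Jun 0.016 (SE 0.14), Ier2 -0.008 (SE 0.14), Fosb 0.057 (SE 0.11) and Egr1 -0.23 (SE 0.13). The lactotrope and mitochondrial lists were higher in the same libraries. Genes of the unfolded protein response had an adjusted p of 0.120 by camera and 0.0331 by fry in either direction. Of these Pdia3 fell adjusted over the list alone (-0.54, SE 0.12), while Calr had -0.38 (SE 0.12), Creld2 -0.75 (SE 0.23) and Chac1 1.13 (SE 0.37). Interferon response genes had an adjusted p of 0.943, with Rtp4 at 0.76 (SE 0.29), Irf9 at 1.10 (SE 0.44), Stat2 at 0.41 (SE 0.19) and Zbp1 at -1.63 (SE 0.79).

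The 13 mitochondrially encoded transcripts were higher as a group, with a median log2 fold change of 0.65 (camera adjusted p = 1.90e-14, but adjusted p = 0.527 with an estimated correlation). Adjusted over the list alone all 13 rose, and over all genes 0 passed. The estimated correlation between these genes was 0.817, well above the preset, so the 13 rises are not independent results. The camera p at the preset treats them as nearly independent and overstates the evidence. mt-Co1 had 0.48 (SE 0.12) and mt-Cytb 0.50 (SE 0.10). These genes held 5.42% and 6.15% of the counts in the controls and 7.76% and 8.98% in the cKO libraries. Without control replicate 1 the median was 0.41. The nuclear transcript Malat1, chosen after its values were seen, had 0.81 (SE 0.14, edgeR adjusted p = 0.212).

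Markers of other pituitary cells were present in the sorted libraries. Pomc, the hormone precursor of corticotropes and melanotropes, stood at 8487 ± 1875 CPM in controls and 6589 ± 787 in cKO, above Lhb in both groups. Lactotrope markers were higher as a group, 6 of 7 with a median of 0.72 (camera adjusted p = 0.000510, but adjusted p = 0.370 with an estimated correlation). Prl, for prolactin, had 447 ± 191 CPM in controls and 1260 ± 15.7 in cKO. Adjusted over the list alone Prl (1.49, SE 0.27) and Edil3 (1.87, SE 0.46) rose, and over all genes neither passed. Gal had 0.98 (SE 0.35). Without cKO replicate 1 the list's median was 1.13. Gh, for growth hormone, had -0.47 (SE 0.69) and Kcnmb2 0.25 (SE 0.53), and somatotrope markers had an adjusted p of 0.964. Dio2 of the thyrotrope markers rose adjusted over the list alone (0.88, SE 0.25), with Pou1f1 at 1.57 (SE 0.62) and an adjusted p of 0.184 for the list. Tshb, for the beta subunit of thyroid-stimulating hormone and chosen after its values were seen, had -1.32 (SE 0.57). Corticotrope markers (adjusted p = 0.387) included Tbx19 at -0.40 (SE 0.36), and melanotrope markers (adjusted p = 0.238) Pcsk2 at -0.02 (SE 0.20). Sox9, a pituitary stem cell marker, rose adjusted over its list alone (1.34, SE 0.28), while Sox2 had 0.64 (SE 0.43) and the list an adjusted p of 0.261.

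Markers of cells from outside the endocrine lineages were low and not called. Adjusted p was 0.255 for endothelial markers, 0.377 for macrophage and leukocyte markers, 0.116 for fibroblast and pericyte markers and 0.186 for erythroid markers. Cdh5 had 9.97 ± 11.7 CPM in controls and 8.78 ± 4.78 in cKO, and Pecam1 10.3 ± 7.88 and 3.78 ± 0.0652. Cd68 had a log2 fold change of -0.71 (SE 0.99), Fcer1g -1.27 (SE 1.61), Col1a2 2.71 (SE 1.92), Rgs5 1.58 (SE 2.03), Hba-a2 -1.33 (SE 1.93) and Hba-a1 -1.87 (SE 2.06). Of the untested pituicyte list Adm had 2.04 (SE 2.22) and Col25a1 -0.24 (SE 1.91). Without control replicate 2 the macrophage and fibroblast lists passed the threshold, and without cKO replicate 1 the erythroid list did.

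The remaining lists were not called. Voltage-gated and potassium channels had an adjusted p of 0.717, with Cacna1h at 0.75 (SE 0.26), Kcnma1 at -0.57 (SE 0.22) and Cacna2d1 at 0.41 (SE 0.23). Cholesterol synthesis had 0.921, with Insig1 at 0.67 (SE 0.23), Dhcr7 at -0.84 (SE 0.39), Sc5d at 0.47 (SE 0.30) and Pmvk at -0.54 (SE 0.34). The extracellular matrix list had an adjusted p of 0.553. The collagen IV genes Col4a2 and Col4a1 had -1.73 (SE 0.39) and -1.27 (SE 0.45), and Spp1 had -0.60 (SE 0.22). Cell cycle genes had an adjusted p of 0.310, with Mcm5 at -1.17 (SE 0.72), Ccna2 at -1.43 (SE 0.93) and Mcm2 at -0.64 (SE 0.51), and Ccnb2 had 48, 75, 0 and 0 counts. Medians of the 26 lists were the same with genes of no count in 1 group set at their bound.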

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

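The newer edgeR method, unrounded counts, thinned libraries, left-out mitochondrial genes and shortened lists were added after seeing the data. The count of 10 genes became 253 without a filter (128 higher, 125 lower), 3 with 1 CPM in 2 libraries, 943 with DESeq2, 256 with limma-voom, 26 with robust=TRUE, 47 with the newer edgeR method, 22 at adjusted p under 0.10, 2 with glmTreat against a factor of 1.5, and 66 to 681 with 1 library left out. The cause was not tested. A fit with 1 library in a group assumes that it varies like the other group. All 10 genes kept their direction in each of these fits of the whole table. The log2 fold change of Gata2 was -1.28 with 1 CPM in 2 libraries and -1.28 with thinned libraries (adjusted p 0.0514), and that of Fshb was -2.01 with 1 CPM in 2 libraries; these lost the call and not the size. Numbers 1 and 2 did not pair the samples (correlation of deviations across genes -0.011). The replicate block gave 7 genes, 6 of them among the 10, and a Gata2 value of -1.29 (adjusted p 0.0643). The calls of Fam13a, Sez6 and Gm47283 and that of the BMP antagonist list (adjusted p 0.376) were also lost. Of the 6 lists called, 0 remained with an estimated correlation and 0 with fry, and 1 passed fry in either direction, which called 3 lists in all. In the simulation an estimated correlation called 0 of 10 shifted lists, so its loss of calls is not evidence of no shift. The simulated genes varied independently, so the preset calls were not tried on genes that vary together. Estimated correlations were 0.817 in the mitochondrial, 0.0616 in the secretory granule and 0.0257 in the gonadotrope list. They were 0.00967, -0.0644 and -0.126 in the immediate-early, BMP antagonist and lactotrope lists, at a preset of 0.01. No called gene changed sign and no called list changed camera's direction, but the median of the BMP antagonist list turned from 0.16 to -0.35 with no filter, -0.08 with 1 CPM in 2 libraries and -0.20 with thinned libraries; uncalled values changed sign 24 times among 12 named genes and 14 times among 8 lists. The libraries split in 3 ways. The real split gave 10 genes and the others 0 and 0 in edgeR. The same splits gave 943, 87 and 67 in DESeq2, 256, 0 and 0 in limma-voom, and 47, 0 and 0 with the newer edgeR method. There are too few splits for a share under 0.05. In each of the other splits a group holds 1 control and 1 cKO library. Differences between genotypes then widen the spread within groups, so few calls were likely in advance. The splits are therefore no evidence for the calls of the real split.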

Other observations

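The tests of explanations in this part were chosen after the results they bear on had been seen, except that the lists of BMP target and immediate-early genes and their camera tests had been fixed before the data were examined. For the lactotrope and mitochondrial patterns, earlier tests were run and replaced: a Prl over Pomc ratio (log2 change 1.92, SE 0.248), thinning to equal totals (median 0.645), the median of the lactotrope markers other than Prl (0.688) and leaving out 24 abundant genes lower in cKO (median 0.646).

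A further 12 genes had an edgeR adjusted p between 0.05 and 0.10, of which 1 was higher and 11 lower in cKO; those other than Pitx1, Lhb and Chgb were chosen after their values were seen. Greb1, a gene induced by estrogen receptor in other tissues, had 18.1 ± 7.10 CPM in controls and 109 ± 10.7 in cKO (log2 fold change 2.58, SE 0.33). Lpl, for lipoprotein lipase, had -3.23 (SE 0.39), Prkg1, for a cGMP-dependent kinase, -3.60 (SE 0.44) and Rflnb -3.21 (SE 0.39). Lama1, for a laminin chain, had -1.85 (SE 0.24), Lrrn2 -1.52 (SE 0.20), Resp18 -1.41 (SE 0.19), Mgat5 -1.18 (SE 0.15) and Clu, for clusterin, -1.15 (SE 0.15). Strip2 had 209 and 135 counts in the controls and 0 in both cKO libraries, at least 70.4-fold lower, with an adjusted p of 0.274. Among tested genes 247 had no count in either cKO library and some in controls, and 138 the reverse.

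Gm21887 and Gm47283 rose together. A gain of the chromosome end that raised the neighbouring gene Mid1 by the same factor is argued against. The log2 fold change of Gm21887 exceeded that of Mid1 by 2.79 (SE 0.45). A smaller gain, or a gain that leaves out Mid1, was not tested. Reads shared between near-identical copies could make 1 signal appear as 2 calls: the ratio of the pair differed by a factor of at most 1.16 between libraries, and all 8 values were not whole. Which copy gave the signal, and whether genotype or strain background set it, stays open, since the strain is given as mixed in both groups.

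Prl and other lactotrope markers were higher in cKO libraries. A lower share of gonadotropes would raise markers of every other type alike only if the mix of those types stayed the same. The lactotrope minus corticotrope difference in mean log2 CPM rose by 1.03 (SE 0.0256). Against somatotrope markers the lactotrope mean rose by 0.913 (SE 0.348) and against melanotrope markers by 1.30 (SE 0.645). Against thyrotrope markers it changed by -0.0314 (SE 0.304). Of the 5 thyrotrope markers tested 4 were higher in cKO, while the hormone gene Tshb was lower. Gh had 1124 and 2375 CPM in the controls and 2149 and 385 in the cKO libraries, so the mix of other cells may differ between libraries. These differences therefore cannot decide whether the share of gonadotropes was lower in the cKO sorts. More lactotrope RNA alone, despite the sort, stays open: it would raise its markers by a common factor, and Prl exceeded the median of the other 6 by 0.806 (SD over these 0.668), whose camera p was 0.0110 at the preset and 0.121 with an estimated correlation. A rise of these genes within gonadotropes through the genotype was not tested and stays open.

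Mitochondrially encoded transcripts were higher in cKO libraries. The fall of a few abundant transcripts would raise all other genes alike, but with library size only the median of all other genes was -0.00638 and that of the mitochondrial genes 0.610 (SD over the genes 0.156). Whether harsher handling of the cKO sorts contributed stays open, since the immediate-early genes do not decide it. Their median was 0.219, with 18 of 24 higher, but the camera adjusted p was 0.370 with an estimated correlation. Fos (-0.006), Jun (0.016) and Ier2 (-0.008) were near no change, and Egr1 had -0.23. Handling and genotype cannot be told apart, since each group is 2 libraries and the labels give no handling record.

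One hypothesis was that lower Grem1, a BMP antagonist, goes with higher BMP target genes. The list gave a camera p of 0.443 with a median of -0.249, so these libraries do not decide it.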
